A study of Homo sapiens with 8 samples.

How the data were processed

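Gene expression was measured by RNA sequencing in 8 samples of fibroblasts grown from human breast tumours. Per the labels' protocols, cells were kept in medium with 20% serum and 10 ng/mL bFGF and were transfected for 5 h with siRNA at 75 nM (the label writes the unit in lower case), 2 times on consecutive days, with harvest 24 h after the second transfection. One Stealth siRNA against POSTN was used (si-POSTN, 4 samples), and the control was a non-targeting siRNA of another supplier (si-Control, 4 samples), so the chemistry of the siRNA differed along with its target. Groups and replicate numbers were taken from the sample titles. The series describes 4 replicates per treatment and no pairing.

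The authors deposited 1 table of counts of reads per gene, not normalized, with 56609 human gene symbols, of which 22445 stood at 0 in all 8 samples. Per the submitters' processing notes, FastQC, MultiQC, STAR, DESeq and DESeq2 were used, without versions. The program that counted reads, the gene annotation, the library kit and whether strand was used are not given in the sources used here. The same notes name the mouse build mm10, whereas the gene symbols are human, and 54916 of them (97.01%, holding 99.48% of the counts) occur in GENCODE release 29. Because the build in the notes and the symbols disagree, no genome coordinates are given. Without strand, reads of genes that overlap on opposite strands cannot be separated, and reads of near-identical family members (KRTAP2-3, the IFITM genes, the HLA genes and several tubulins) may be split between copies, so values of such genes are uncertain.

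Total counts ran from 18734471 to 37149850 per sample. A gene with 3 counts, taken as the floor, corresponds to between 0.0808 and 0.16 CPM (counts scaled to equal library size), and this floor covers counting error only. Genes passing filterByExpr at its defaults were tested (15364 genes) with edgeR 4.0.16 in R 4.3.3: TMM normalization, glmQLFit and glmQLFTest, group as the only term. Standard errors are the absolute log2 fold change divided by the square root of F. P values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05, and "rose" or "fell" is used of genes past it. CPM values are on TMM-scaled library sizes and are given as mean ± SD.

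Before the data were examined, 23 gene lists (548 genes) were fixed, of which 493 genes were tested and 6 were matched by an older symbol. Lists with at least 5 tested members (21 lists) were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, two-sided, adjusted by Benjamini-Hochberg over the lists. POSTN is in none of the lists. Camera with an estimated correlation and the self-contained test fry were alternatives. The genes named in the text follow a rule fixed at the same time: POSTN, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group, a gene symbol and no overlap between groups, the 5 smallest p values not yet named, and up to 4 members of each list with the smallest p. Other members are given by symbol only. A named list member and a test that needed a withheld gene are not reported here. Where a single exception within a list is named with a value outside this rule, it was chosen after its values were seen.

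Words in 3′ UTRs were examined after the fold changes had been seen. Each tested gene with an annotated 3′ UTR of at least 50 bases in GENCODE 29 was searched (12507 genes without POSTN, 81.41% of those tested). The log2 fold change, with extreme values clipped, was related to the presence of each 7-base word held by at least 50 genes (16172 words). Covariates were 3′ UTR length, base composition, the share of CG pairs and mean expression. The words were ranked by t with Benjamini-Hochberg adjustment. The joined site is the run of bases formed by the leading overlapping words. Genes not searched count neither as having nor as lacking a site.

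The steps were tested on simulated data, counts drawn for the 15364 tested genes from the real means and library sizes with 4 against 4 samples. At adjusted p under 0.05, edgeR recovered 38% of 50 genes changed 1.2-fold, 76% of 50 changed 1.5-fold, 80% of 50 changed 2-fold and 98% of 50 changed 3-fold, and 10 unchanged genes made up 5.88% of the calls. In this simulation a change of 1.2-fold was therefore missed more often than found. Only 200 genes outside a planted list were simulated as changed, against 5936 genes called in the real data. The Benjamini-Hochberg cutoff on p was thus stricter in the simulation, so the shares recovered do not carry over to the real data.

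Alternatives fixed before the data were examined were RLE factors, library totals alone and upper-quartile factors in place of TMM, the DESeq2 1.42.0 Wald test and limma-voom in place of edgeR, no filter on low counts or a mean of at least 5 CPM, the replicate number as a block, POSTN left out of library totals, a threshold of 0.01, each sample left out in turn, and the other list tests. Restricting genes or list members to those without a 6-base part of the joined site was added after the data were seen. Alternatives written for tables without counts were not needed. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, word scans and plots.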

Results

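To examine how periostin shapes the transcriptome of tumour stroma, RNA was sequenced from fibroblasts cultured from human breast carcinoma (cancer-associated fibroblasts) after transfection with a control siRNA (si-Control, 4 samples) or an siRNA against POSTN, which encodes the secreted matricellular protein periostin (si-POSTN, 4 samples). The series concerns periostin-positive stromal cells and the invasion of lymphatic and blood vessels by cancer cells. Read counts summed to 24744021, 21146159, 37149850 and 24897989 in si-Control replicates 1 to 4. They summed to 20214828, 34014832, 23264780 and 18734471 in si-POSTN replicates 1 to 4. The labels do not say whether replicates were separate cultures or donors, so p values measure only the spread between these samples, which may be technical. Correlations of log2 CPM (counts scaled to equal library size) were 0.991 to 0.994 within groups and 0.984 to 0.986 between groups. The first principal component (44.7% of the variance) separated the groups, and no pair of libraries matched within sampling noise (chi-square per degree of freedom 2.52 to 8.44 within groups).

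POSTN was nearly removed. It stood at 263, 288, 272 and 272 CPM in the 4 si-Control libraries and at 3.24, 3.11, 3.92 and 2.96 CPM in the 4 si-POSTN libraries. The group means were 274 ± 10.2 and 3.31 ± 0.424 CPM (SD, n = 4 each), so 1.21% of the control level was left, an 82.7-fold decrease (log2 fold change −6.37, SE 0.07; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.00e-23). All 8 libraries therefore carried the POSTN level that their labels call for.

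**Figure D1:**
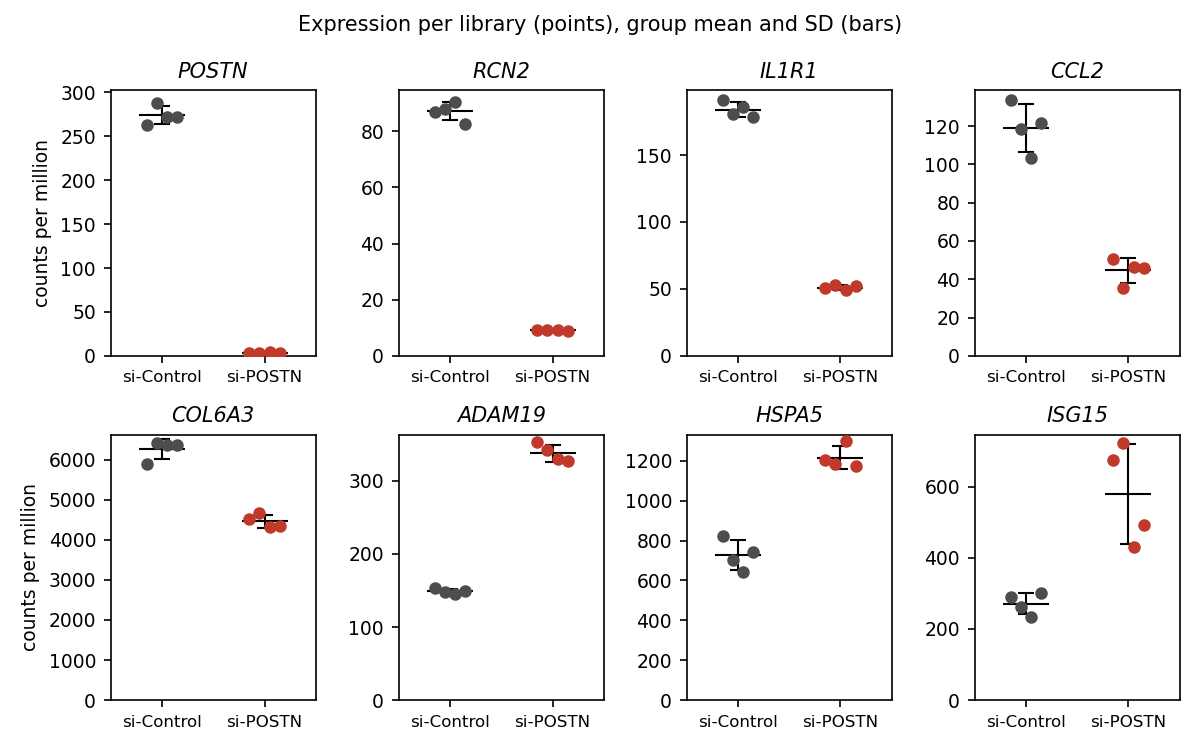
CPM (y axes, linear, each starting at 0) of 8 genes in the 4 si-Control (grey) and 4 si-POSTN (red) libraries; points are libraries, horizontal lines group means and error bars SD. POSTN fell from 274 to 3.31 CPM on average, RCN2, IL1R1, CCL2 and COL6A3 were lower and ADAM19, HSPA5 and ISG15 higher in all 4 si-POSTN libraries.

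Beyond its target, si-POSTN was followed by lower expression of matrix and inflammatory genes and by higher expression of interferon-stimulated and endoplasmic reticulum stress genes. The steepest fall after POSTN was that of RCN2, a calcium-binding protein of the endoplasmic reticulum, from 87.1 ± 3.22 to 9.11 ± 0.177 CPM (n = 4 each, 9.55-fold). The transcription factor POU2F2 fell 7.66-fold, from 8.95 ± 1.04 to 1.19 ± 0.540 CPM, and GALNT1, which starts mucin-type O-glycosylation, fell 5.11-fold, from 72.7 ± 1.73 to 14.2 ± 0.619 CPM. Further down the list were CYB561 (4.43-fold), the nuclear import receptor IPO11 (4.40-fold), RASD1 (4.27-fold), URI1 (4.13-fold), the ion channel TRPA1 (3.84-fold), XIRP1 (3.79-fold) and IL1R1, the receptor through which interleukin-1 signals (184 ± 5.65 to 51.1 ± 1.53 CPM, 3.60-fold). Hexokinase 1 (HK1, 3.54-fold), the fatty acid ligase ACSL4 (3.28-fold), SARAF (2.67-fold), AZIN1 (2.56-fold) and TCF3 (2.54-fold) had the smallest p values of the remaining genes. Adjusted p values for these 15 falls lay between 6.96e-20 (RCN2) and 3.31e-07 (XIRP1; edgeR quasi-likelihood, Benjamini-Hochberg).

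Rises were smaller. The HLA-region transcript HCP5 rose 3.49-fold, from 2.16 ± 0.179 to 7.51 ± 1.88 CPM, and BST2, an interferon-induced antiviral membrane protein, 3.39-fold, from 6.53 ± 1.77 to 21.5 ± 11.3 CPM (n = 4 each). BST2 was uneven within si-POSTN, with 29.1 and 33 CPM in replicates 1 and 2 and 10.6 and 13.1 CPM in replicates 3 and 4. KRTAP2-3 (3.24-fold, a keratin-associated gene with near-identical copies, so of uncertain assignment), ANKRD52 (2.65-fold, 107 ± 0.979 to 282 ± 4.74 CPM), ATP6V0D2 (2.53-fold), LINC00973 (2.40-fold), FRK (2.39-fold), the metalloprotease ADAM19 (2.27-fold, 149 ± 3.22 to 338 ± 11.6 CPM), SLC25A15 (2.25-fold) and CPA4 (2.24-fold) completed the 10 largest rises. Their adjusted p values ran from 1.02e-16 (ANKRD52) to 3.31e-05 (BST2; edgeR quasi-likelihood, Benjamini-Hochberg).

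Of 15364 genes tested, 5936 (38.6%) changed, 2734 upward and 3202 downward (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median absolute log2 fold change of the changed genes was 0.32, and 316 genes changed by 2-fold or more, 93 upward and 223 downward. In 5432 tested genes (35.4%) the 4 libraries of one group lay entirely above those of the other, against 2.86% given by chance. The share of changed genes that rose was 46.1%, and it depended on scaling: it was 57.4% with upper-quartile factors (3584 rose, 2657 fell) and 65% with library totals alone (4287 rose, 2303 fell). With a mean of at least 5 CPM required, 126 genes changed by 2-fold or more among 10552 tested.

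**Figure D2:**
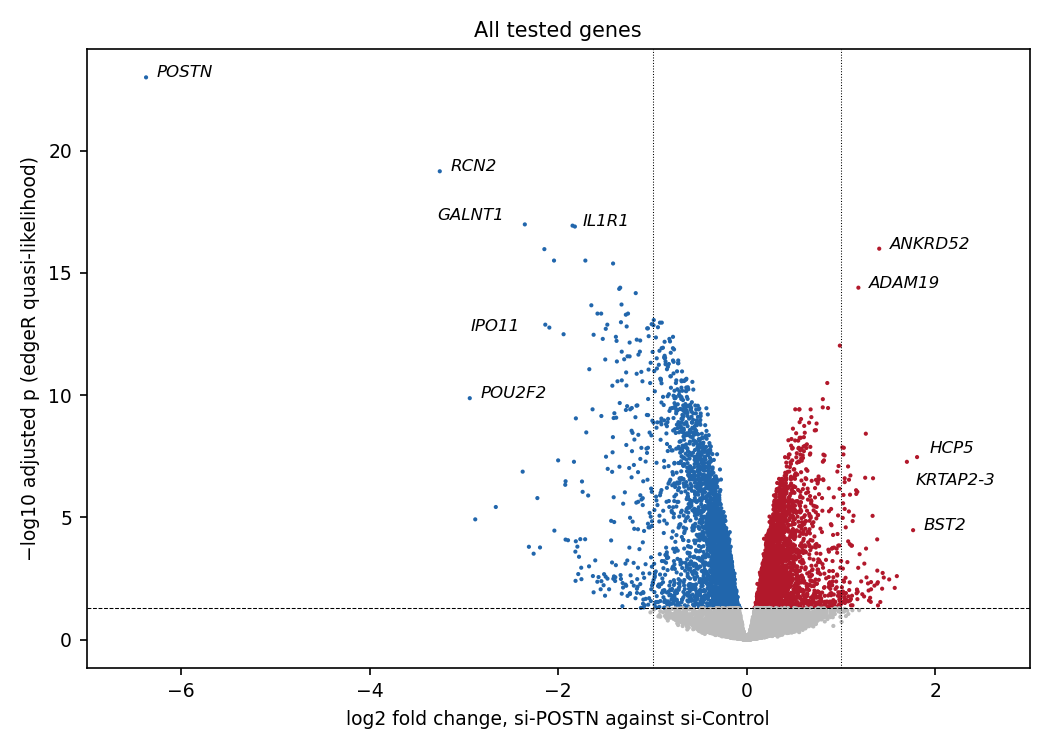
Each point is 1 of 15364 tested genes; the x axis is the log2 fold change of si-POSTN against si-Control and the y axis the −log10 of the edgeR quasi-likelihood adjusted p. Red genes rose and blue genes fell past adjusted p of 0.05 (dashed line), grey genes did not pass, and dotted lines mark 2-fold; POSTN lies at −6.37 and RCN2 at −3.26.

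The steep falls shared a short sequence. Among all 7-base words in annotated 3′ UTRs, AACAAAA (t = −16.4), CAACAAA (t = −16.2) and GCAACAA (t = −13.5) were the words most associated with lower fold changes. They overlap to form GCAACAAAA, whereas a single shuffle of the fold changes gave no word under −3.51. AACAAAA was present in 53.2% of the 188 searched genes that fell 2-fold or more and in 28.3% of searched genes without a 2-fold change (two-sided Fisher's exact test, p = 1.38e-12). The word was picked as the leading one on these same fold changes, and the test does not allow for 3′ UTR length. Its p value therefore describes the enrichment and is no separate support. Of the 15 genes with the steepest or surest falls named here, 12 hold a 7-base part of the site in the 3′ UTR, and IPO11, TRPA1 and XIRP1 do not. The median log2 fold change went from 0.06 in 4593 genes with no 6-base part to −0.07 with a 7-base part, −0.17 with an 8-base part and −0.30 in the 166 genes with the whole site, of which 59% fell and 2.41% rose. A 7-base part occurs in 34.4% of searched genes without a 2-fold change in either direction, and the share is given beside most gene lists below. Neither these classes nor the list members with and without a part were matched for 3′ UTR length. A longer 3′ UTR has more room for a part, so the classes also differ in length.

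**Figure D3:**
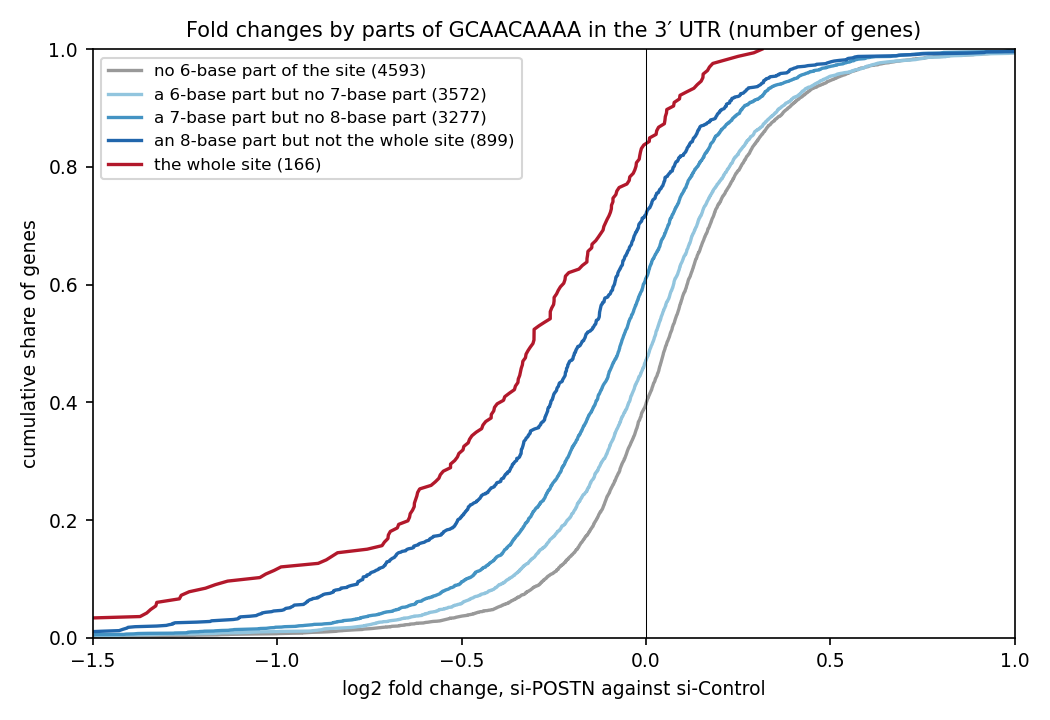
Cumulative share of genes (y axis) at or below each log2 fold change of si-POSTN against si-Control (x axis), for 5 classes of genes by the longest part of GCAACAAAA in their annotated 3′ UTR, with the number of genes in each class. The curves move to lower values as the part gets longer. The median goes from 0.06 in 4593 genes with no 6-base part to −0.30 in 166 genes with the whole site. POSTN is left out, and the classes are not matched for 3′ UTR length.

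Of 21 collagen chain genes, 17 fell and 1 rose, with the same counts adjusted over the list alone and a median log2 fold change of −0.42. COL5A3 fell from 42.1 ± 1.76 to 22.5 ± 0.330 CPM (1.87-fold), COL8A1 from 125 ± 4.34 to 73.6 ± 5.26 CPM (1.70-fold), COL8A2 1.43-fold and the abundant COL6A3 from 6263 ± 247 to 4463 ± 158 CPM (1.40-fold). The exception, chosen for mention after its values were seen, was COL1A1, a chain of the main fibrillar collagen I, which rose by 0.16 (SE 0.04) on the log2 scale. COL1A2, COL5A1 and COL11A1 did not pass. Collagen list members differed from other genes (camera, adjusted p = 2.31e-07; adjusted p = 0.175 with an estimated correlation), and 57.1% of them hold a 7-base part of the site, with a median of −0.45 in those and −0.18 in the 9 members without.

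Among 30 matricellular, elastic-fibre and proteoglycan genes, 21 fell and 3 rose, also adjusted over the list alone (median −0.36). MFAP4, a microfibril-associated protein, fell 1.89-fold (140 ± 11.6 to 74.5 ± 2.00 CPM), thrombospondin 1 (THBS1) 1.54-fold, fibulin 1 (FBLN1) 1.59-fold and LTBP2, a latent TGF-beta binding protein family member, 1.43-fold, while SPARC, ELN and NOV rose. The list was called (camera, adjusted p = 1.99e-05; adjusted p = 0.257 with an estimated correlation; 26.7% with a 7-base part, with a median of −0.38 in those and −0.26 in the 22 without). The 9 members without even a 6-base part had a median of −0.13, with 8 lower and 1 higher. Of 28 matrix protease and inhibitor genes, 15 fell and 4 rose, by both adjustments. The stromelysin MMP11 fell 2.54-fold, the gelatinase MMP2 1.33-fold and ADAMTS12 1.48-fold, whereas ADAM19 rose. The protease list was called (camera, adjusted p = 0.0219, and 0.0553 without si-Control replicate 1; adjusted p = 0.267 with an estimated correlation; 40.7% with a 7-base part). Integrin and focal adhesion genes followed the same direction, with 15 of 24 lower and 4 higher (6 higher adjusted over the list alone): ITGB1, the common beta chain of most matrix-binding integrins, fell from 4042 ± 61.2 to 3003 ± 45.3 CPM (1.35-fold), ITGA4 1.48-fold, ITGAV 1.43-fold and PARVA 1.39-fold. Their list was called (camera, adjusted p = 0.00515; adjusted p = 0.175 with an estimated correlation; 37.5% with a 7-base part). Genes for collagen processing and cross-linking went both ways, 6 higher and 10 lower of 24 (11 lower adjusted over the list alone). LOX (1.31-fold), PLOD2 (1.47-fold) and ADAMTS2 (1.24-fold) fell and the collagen chaperone SERPINH1 rose 1.24-fold (camera, adjusted p = 0.351, but 0.0168 with fry; 16.7% with a 7-base part). LOX, PLOD2 and ADAMTS2 hold such a part and SERPINH1 does not. The median was −0.35 in the 4 members with a 7-base part and −0.01 in the 20 without.

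TGF-beta target genes were lower in 16 of 20 cases and higher in 0, also adjusted over the list alone (median −0.26). ID3 fell 1.94-fold, the TGF-beta pathway inhibitor SKIL 1.56-fold, LTBP2 1.43-fold and the cell cycle inhibitor CDKN2B 1.41-fold (camera, adjusted p = 1.99e-05; adjusted p = 0.0715 with an estimated correlation; 45% with a 7-base part, with a median of −0.27 in those and −0.26 in the 11 without). Contractile genes of myofibroblasts were mixed, with 10 of 19 lower and 4 higher by both adjustments. MYLK, the myosin light chain kinase, fell 1.49-fold, SYNPO2 1.47-fold, CDH11 1.34-fold and CNN2 1.27-fold, while TAGLN, MYL9, TPM1 and PDLIM7 rose. The myofibroblast marker ACTA2 did not pass. A 7-base part is held by 3 members of this list, MYLK and SYNPO2 among them, but not by CDH11 or CNN2. The median was −0.55 in those 3 and −0.07 in the 16 without. The contractile list's call (camera, adjusted p = 0.0422; adjusted p = 0.560 with an estimated correlation; 15.8% with a 7-base part) was lost without si-Control replicate 2, 3 or 4 or without si-POSTN replicate 1 or 3, with adjusted p up to 0.0795. It was also lost with library totals (0.0868), upper-quartile factors (0.0636) and the 5 CPM filter (0.0930). YAP/TAZ target genes, 5 higher and 9 lower of 21 by both adjustments, were not called (camera, adjusted p = 0.142, but 0.0482 without a low-count filter and 0.00247 with fry), although ASAP1 (1.55-fold), RBMS3 (1.54-fold), CYR61 (1.41-fold) and CRIM1 (1.34-fold) fell; 33.3% of this list hold a 7-base part, with a median of −0.06 in those and −0.08 in the 14 without.

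The largest shift of any list was that of inflammatory cytokines and their regulators. Of 28 genes, 23 fell and 1 rose, by both adjustments, with a median log2 fold change of −1.17. The chemokine CCL2 fell from 119 ± 12.6 to 44.6 ± 6.37 CPM (2.69-fold), the hyaluronan-binding protein TNFAIP6 from 222 ± 30.5 to 70 ± 10 CPM (3.18-fold), LIF from 84.8 ± 16.5 to 31.9 ± 2.41 CPM (2.65-fold) and the adhesion molecule ICAM1 from 422 ± 24.8 to 211 ± 12.6 CPM (2.00-fold; n = 4 each). IL6, IL1A, IL1B, CXCL1, CXCL8, CSF3 and PTGS2 were among the other members that fell. CCL5, an interferon-responsive chemokine, rose. The list stood apart from other genes (camera, adjusted p = 8.64e-10; adjusted p = 0.267 with an estimated correlation), and 32.1% of its members hold a 7-base part. The 10 members with no 6-base part were all lower, 8 of them past the threshold, with a median of −1.05.

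Interferon-stimulated genes moved the other way. Of 36 genes, 32 rose and 0 fell (33 rose adjusted over the list alone), with a median log2 fold change of 0.68. The ubiquitin-like protein ISG15 rose from 271 ± 30.1 to 580 ± 141 CPM (2.14-fold), IFI44L from 116 ± 17.4 to 242 ± 45.6 CPM (2.10-fold), IFI27 from 85.4 ± 9.77 to 173 ± 30.3 CPM (2.03-fold) and OAS2, a sensor of double-stranded RNA, from 172 ± 20.5 to 334 ± 62.4 CPM (1.95-fold). IFIT2, IRF9, CXCL10 and CXCL11 did not pass. The rise was larger in si-POSTN replicates 1 and 2 (ISG15 675 and 721 CPM) than in replicates 3 and 4 (431 and 491 CPM), and IFI44L, OAS2 and IFI27 had the same order. The members varied together between libraries, with an estimated correlation of 0.86, and 22.2% of them hold a 7-base part. The list was called by camera with the preset correlation (adjusted p = 8.58e-10) but not with an estimated one (adjusted p = 0.381). Fry also called it (adjusted p = 0.00825).

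Genes of the unfolded protein and integrated stress response were higher in 15 of 28 cases and lower in 3, by both adjustments (median 0.25). The endoplasmic reticulum chaperone HSPA5 rose from 728 ± 76.9 to 1216 ± 56 CPM (1.67-fold), HERPUD1 1.61-fold and HYOU1 1.58-fold, while ATF5 fell 1.39-fold (camera, adjusted p = 2.79e-04; adjusted p = 0.283 with an estimated correlation; 28.6% with a 7-base part). Of 31 cholesterol and fatty acid synthesis genes, 18 fell and 1 rose (19 and 1 adjusted over the list alone; median −0.15). The sterol demethylation enzyme MSMO1 fell 2.42-fold (264 ± 23.6 to 109 ± 3.28 CPM), the elongase ELOVL6 2.24-fold and the desaturase FADS1 1.77-fold (camera, adjusted p = 1.43e-04; adjusted p = 0.257 with an estimated correlation; 22.6% with a 7-base part).

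Factors that act on lymphatic and blood vessels were lower in 11 of 21 cases and higher in 1 (11 and 2 adjusted over the list alone; median −0.17). Angiopoietin 1 (ANGPT1) fell from 32.6 ± 2.04 to 11.4 ± 0.556 CPM (2.88-fold), hepatocyte growth factor (HGF) from 37.9 ± 1.67 to 17 ± 1.30 CPM (2.25-fold), FGF7 from 63.3 ± 2.94 to 32 ± 1.81 CPM (1.97-fold) and the semaphorin and VEGF co-receptor NRP1 from 416 ± 13.9 to 251 ± 5.22 CPM (1.66-fold). VEGFC, the main lymphatic growth factor, fell and VEGFA did not pass. The list was called (camera, adjusted p = 0.00244; adjusted p = 0.257 with an estimated correlation). A 7-base part of the site is held by 66.7% of its members, and their median was −0.35 against 0.01 in the 7 without.

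**Figure D4:**
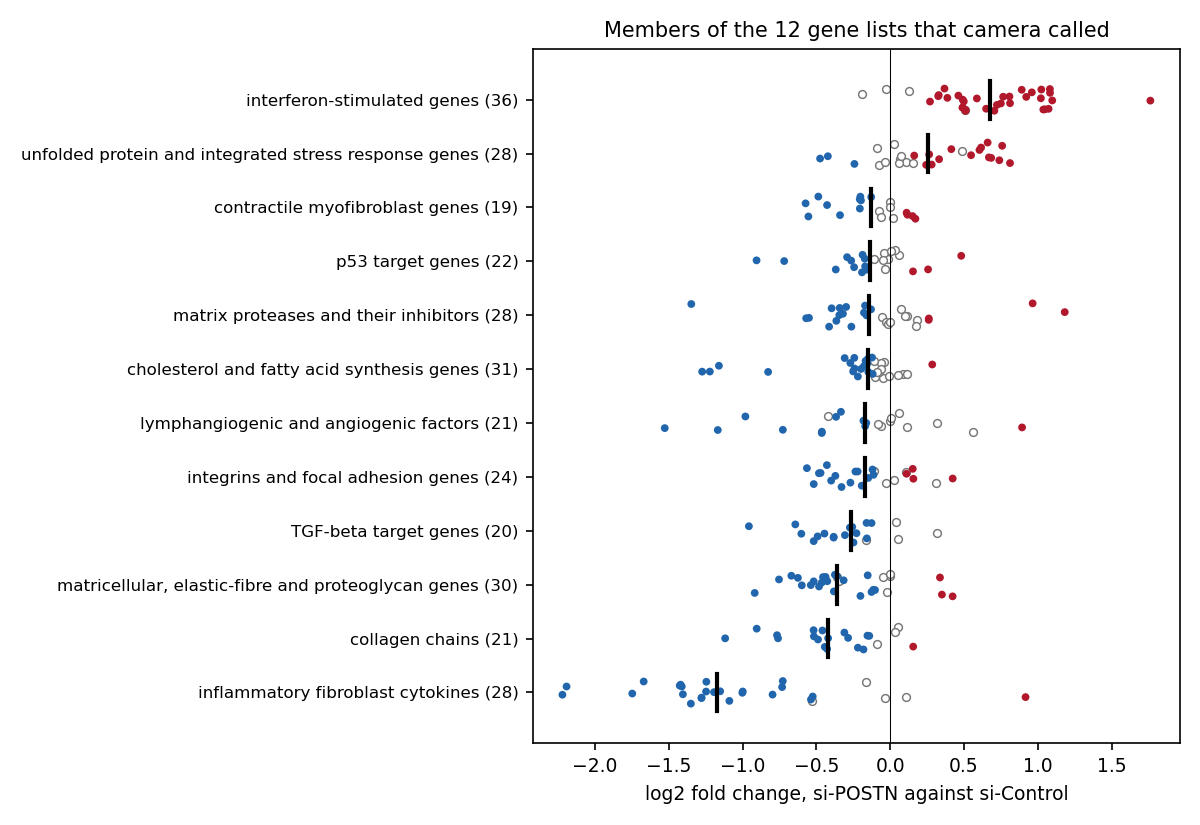
Log2 fold change of si-POSTN against si-Control (x axis) of the tested members of the 12 lists that camera called with a preset correlation, with the number of tested members in parentheses. Red points rose, blue points fell, open points did not pass adjusted p of 0.05, and black bars are medians, from −1.17 (inflammatory cytokines) to 0.68 (interferon-stimulated genes).

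Of 22 p53 target genes, 11 fell and 3 rose by both adjustments, ZMAT3 (1.87-fold), BTG2 (1.65-fold) and PLK3 (1.29-fold) falling and GDF15 rising 1.40-fold, while the central targets CDKN1A and MDM2 did not pass. This call (camera, adjusted p = 0.0487; adjusted p = 0.267 with an estimated correlation; 45.5% with a 7-base part) was lost without any 1 library other than si-Control replicate 1 or si-POSTN replicate 2, with adjusted p up to 0.109. It was also lost with RLE factors (0.0501), library totals (0.114), upper-quartile factors (0.0781) and the 5 CPM filter (0.103). Hypoxia and glycolysis genes were split, 7 higher and 6 lower of 26 by both adjustments, with HK1, CA12 (1.33-fold) and PFKFB3 (1.40-fold) lower and the glucose transporter SLC2A3 1.47-fold higher. Their median (0.04) and mean (−0.05) differed in sign (camera, upward, adjusted p = 0.787, but downward with fry, 0.00675; 38.5% with a 7-base part). Cell cycle genes were little moved, 4 higher and 6 lower of 38 (2 and 5 adjusted over the list alone): MCM4 (1.27-fold), MCM6 (1.34-fold) and PCNA (1.18-fold) fell, MCM5 rose 1.37-fold, and the list was not called (camera, adjusted p = 0.401; 13.2% with a 7-base part), its direction turning from up to down with a mean of at least 5 CPM required.

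In all, camera called 12 of the 21 lists with the preset correlation, 0 with an estimated one, where 3 lists had an unadjusted p under 0.05, and fry called 16. Other divisions of the 8 libraries into 4 and 4 gave a median of 3 called lists and up to 11. The high counts came from divisions that left most libraries of a group together and so kept part of the real difference. Because the calls depended on the list test, the member counts and fold changes describe the groups better than the preset p values.

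Of 10 pericyte and smooth muscle markers tested, 4 fell and 2 rose by both adjustments: RGS5 (3.11-fold, 10.9 ± 0.674 to 3.48 ± 0.500 CPM), NOTCH3 (1.61-fold, 37.5 ± 3.01 to 23.2 ± 1.25 CPM), PDGFRB (1.52-fold, 515 ± 38.7 to 339 ± 11.6 CPM) and CSPG4 (1.33-fold, 526 ± 22.2 to 395 ± 25.1 CPM) fell. PDGFRB and CSPG4 are also fibroblast genes. The list was not called (camera, adjusted p = 0.0741; 22.2% with a 7-base part), but it was with library totals (0.0472), without a low-count filter (0.0081) and with fry (6.28e-05). Of 11 endothelial and lymphatic endothelial markers, VWF fell (7.35 ± 0.719 to 5.25 ± 0.900 CPM) and 10 did not pass, among them PECAM1 at 9.61 and 8.29 CPM, EGFL7 at 12 and 10.3 CPM and TEK at 0.440 and 0.608 CPM. EGFL7 passed with the replicate block (adjusted p = 0.0463) and without si-POSTN replicate 3 (0.0186), and PECAM1 without si-Control replicate 3 (0.0291). The list was not called (1 lower adjusted over the list alone; camera, adjusted p = 0.418; 54.5% with a 7-base part). Of 10 epithelial markers, ELF3 fell (1.39 to 0.399 CPM) and ESR1 rose (0.897 to 1.46 CPM, lost without any 1 library other than si-POSTN replicate 2 and with DESeq2, limma-voom, no low-count filter or the replicate block, and not among the calls adjusted over the list alone), while CLDN4 (1.04 and 1.41 CPM) and KRT7 (18 and 17 CPM) did not pass (camera, adjusted p = 0.998, with a direction that changed between settings; 22.2% with a 7-base part). Of 20 leukocyte markers 4 could be tested: CD68, a lysosomal protein that fibroblasts also make, rose 1.43-fold (14.9 ± 1.39 to 21 ± 2.17 CPM), and CD14, CSF1R and HLA-DRA stayed at 0.342 to 2.44 CPM without passing, with 1 higher adjusted over the list alone. Of 12 adipocyte markers, the 3 tested (PPARG, PLIN4 and GPD1) did not pass over all genes and lay at 0.712 to 2.60 CPM, with 1 higher and 1 lower adjusted over the list alone. PPARG passed with library totals (adjusted p = 0.0397) and without si-Control replicate 1 (0.0438), and GPD1 without si-POSTN replicate 4 (0.0318).

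Mitochondrially encoded mRNAs made up 2.77 to 3.20% of counts in all libraries. The 10 most abundant genes made up 10.7 to 11.3% in si-Control and 10.4 to 10.5% in si-POSTN, without overlap. Of 13 mitochondrially encoded mRNAs, MT-CO1, MT-CO3 and MT-CYB fell by 0.12 to 0.18 and MT-ND3 rose by 0.31 on the log2 scale, by both adjustments (camera, adjusted p = 0.839; the median, −0.02, and the mean, 0.03, differed in sign). Of 28 ribosomal protein genes 1 rose and 7 fell (0 and 6 adjusted over the list alone), RPL4, RPL15, RPLP0 and RPL3 by 0.13 to 0.14 (camera, adjusted p = 0.626; 9.09% with a 7-base part). With library totals alone, the falls of MT-CO1, MT-CO3, MT-CYB, RPL3, RPL4, RPL15 and RPLP0 no longer passed and the direction of both lists turned. With upper-quartile factors the same falls except that of MT-CO1 no longer passed (adjusted p = 0.0569 to 0.115). With 1 library left out in turn, MT-ND3 and RPL3 kept their calls in 4 of 8 fits, MT-CO3 and MT-CYB in 5 and RPLP0 in 7, and MT-ND3 did not pass with DESeq2 (adjusted p = 0.187).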

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

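The spread within groups was examined for 114 named genes in both groups, 228 groups of 4 libraries in all. A library stood apart from the other three when its gap to the nearest of them exceeded Dixon's 95% limit, and 11 groups met this, against 11.4 given by chance at 1 in 20, so no single case calls for an explanation.

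In si-Control replicate 1, POU2F2 stood at 10.5 CPM (8.33 to 8.57 in the other si-Control libraries), ACSL4 at 382 (339 to 341), COL6A3 at 5895 (6364 to 6418), MMP2 at 5091 (5322 to 5340) and RPL15 at 651 CPM (682 to 684). In si-Control replicate 4, HGF stood at 35.4 CPM (38.5 to 39.0) and ESR1 at 0.544 CPM (0.998 to 1.03). In si-POSTN replicate 2, IPO11 stood at 4.49 CPM (4.04 to 4.10 in the other si-POSTN libraries). In si-POSTN replicate 3, MMP2 stood at 3877 CPM (3978 to 3989) and LIF at 35.5 CPM (30.4 to 31.0). In si-POSTN replicate 4, GPD1 stood at 1.04 CPM (0.580 to 0.625).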

How the results depend on the processing

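Restriction to genes or list members without a 6-base part of GCAACAAAA was chosen after the data were seen; the other settings were not. POSTN stayed between −6.46 and −6.33 on the log2 scale when libraries were left out in turn. Over the same 8 fits, 5280 to 5790 genes changed, 2374 to 2659 rose, 2906 to 3131 fell, 327 to 366 changed by 2-fold or more, 10 to 12 lists were called and 283 to 305 list members changed. Of 102 named genes past the threshold besides POSTN, 93 kept direction and call under every alternative that tested them, 9 lost the call in at least 1 and 0 changed direction. There were 18 alternatives, and 8 of these genes were not tested with the 5 CPM filter. DESeq2 called 5630 genes, voom 5962, edgeR without a filter 5565, with RLE factors 5935, with POSTN left out of totals 5934 and at adjusted p under 0.01 4312.

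With library totals alone 4287 genes rose, which follows from the scale, since it raises the median log2 fold change of all genes from 0.01 to 0.09. With a mean of at least 5 CPM, 126 genes changed 2-fold or more among 10552 tested, against 316 among 15364 with the default filter. All changed genes dropped less, from 5936 to 5385. The filter thus took away a larger share of the genes changed 2-fold or more than of all changed genes. With an estimated correlation 0 lists were called. For TGF-beta targets that correlation was 0.0079, below the preset 0.01, yet the call was lost (camera with an estimated correlation, adjusted p = 0.0715). A higher correlation between members therefore does not account for the loss in that list, and what does was not tested. Among 4593 genes without a 6-base part 1752 changed (1113 higher, 639 lower). The total follows the fewer genes tested, but 63.5% of the changed genes were higher, against 46.1% of all changed genes, without matching for 3′ UTR length. With this restriction 5 of the 14 lists that could still be tested were called by camera with the preset correlation (matricellular, inflammatory, interferon-stimulated, cholesterol and unfolded protein response genes). Only the list members were restricted here, and they were compared with all other tested genes, with or without a part. Genes holding a part had lower medians, so this comparison leans upward for the restricted members. Proteases (0.581), integrins (0.378), p53 targets (0.468) and contractile genes (0.831, turned to higher) lost the call, with fewer members, and the cause was not tested. Collagen chains, TGF-beta targets and lymphangiogenic factors kept under 5 members and could not be tested.

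Directions of uncalled results turned as follows (adjusted p); the cause was not tested. For epithelial markers these were 0.997 with RLE factors, 0.868 with library totals, 0.961 with upper-quartile factors, 0.993 with DESeq2, 0.830 with no filter, 0.905 with the replicate block, 0.447 with fry and 0.827 to 0.976 over the 8 fits with a library left out (turned at 0.963, 0.975, 0.971 and 0.941 without si-Control replicate 2 or 3 or si-POSTN replicate 1 or 4). Mitochondrially encoded mRNAs turned with library totals (0.868) and without si-Control replicate 4 (0.783) or si-POSTN replicate 2 (0.727; range 0.369 to 0.987), ribosomal proteins with library totals (0.847) and without the same libraries (0.490 and 0.963; range 0.199 to 0.963), cell cycle genes with the 5 CPM filter (0.792), and hypoxia and glycolysis genes with fry (0.00675). CSF1R turned to a log2 fold change of 0.0135 with library totals and to 0.0986 and 0.034 without si-Control replicate 1 or si-POSTN replicate 3 (range −0.208 to 0.0986). PLIN4 turned to −0.0463 without si-Control replicate 1 (range −0.0463 to 0.380).

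The replicate block gave 6002 changed genes. Deviations of libraries with the same number correlated at −0.01 to 0.03, and 1 of 4 si-Control libraries correlated best with its own number, so the numbers were not taken as pairs. Depth limits genes near the floor of 0.0808 to 0.16 CPM, among them most leukocyte and adipocyte markers.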

Other observations

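The 6 gene lists of this part, the genes named from them, the tests of base composition, of a response to the loss of periostin and of TTGTGTG in interferon-stimulated genes were chosen after fold changes had been seen; outcomes of the other tests were set down before those tests were run. Of 31 genes for moving and glycosylating proteins in the endoplasmic reticulum, 20 rose and 6 fell (20 and 6 adjusted over the list alone; median log2 fold change 0.20; camera, adjusted p = 3.87e-04; adjusted p = 0.180 with an estimated correlation; 31% with a 7-base part of GCAACAAAA). SSR3 of the translocon-associated complex rose from 298 to 439 CPM (log2 fold change 0.56, SE 0.04), SEC11C of the signal peptidase by 0.65 (SE 0.08) and GMPPA by 0.60 (SE 0.05), while DDOST fell by 0.20 (SE 0.03). Tubulin genes rose in 8 of 11 cases and fell in 0 (8 and 0 adjusted over the list alone; median 0.23; camera, adjusted p = 3.87e-04; adjusted p = 0.180 with an estimated correlation; 18.2% with a 7-base part), TUBA1B from 76.1 to 108 CPM (0.51, SE 0.04) and TUBB6 by 0.42 (SE 0.05). Some tubulin genes are near-identical, so shares between them are uncertain.

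Antigen presentation genes of MHC class I rose in 10 of 17 cases and fell in 1 (11 and 1 adjusted over the list alone, median 0.24, 6.25% with a 7-base part). Camera gave an adjusted p of 0.00228 with the preset and 0.452 with an estimated correlation. HLA-F rose by 0.76 (SE 0.19), PSMB9 by 0.60 (SE 0.10), TAP1 from 224 to 334 CPM (0.58, SE 0.06) and NLRC5 by 0.57 (SE 0.08). B2M (0.05, SE 0.05) and PSMB10 (−0.07, SE 0.07) were among those that did not pass. Other proteasome subunits were not called (7 higher and 3 lower of 31, 6 and 3 adjusted over the list alone; camera, adjusted p = 0.464; 32.3% with a 7-base part). Genes for semaphorins and plexins, which guide axons and vessels, listed with the plexin-domain-containing PLXDC1 and PLXDC2, which are not plexins, fell in 12 of 23 cases and rose in 2, by both adjustments (median −0.16; camera, adjusted p = 0.00598; adjusted p = 0.180 with an estimated correlation): SEMA5A fell from 259 to 108 CPM (−1.26, SE 0.05) and PLXND1 by 0.54 (SE 0.04), and PLXDC1 and PLXDC2 are 2 of the 12 falls. Of this list 52.2% hold a 7-base part of GCAACAAAA, and the median was −0.43 in those and −0.09 in the 11 without.

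Of the 35 ways to divide the 8 libraries into 4 and 4, 1, the real one, gave as many changed genes (5936), genes in 1 direction (2734 higher, 3202 lower) or genes changed 2-fold (316). With edgeR the highest count of any other division was 0, with 142 to 1366 genes at an unadjusted p under 0.05 against 7125 in the real one. A first rank of 35 is the strongest outcome these divisions allow, so it argues against a chance arrangement without excluding it. The size of the gap adds little, because a division that mixes the groups takes their difference into its own spread. For lists, 1 of 35 divisions gave as many (12), yet the highest of the others was 11 and 7 of 34 gave 10 or more. All 7 left most libraries of a group together, so they kept part of the real difference between groups. Their counts therefore cannot show how readily the preset correlation calls lists without such a difference. Divisions that mixed the groups evenly called 0 to 3 lists.

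Beside POSTN, steep falls were enriched for the 3′ UTR word AACAAAA (odds ratio 2.84 within 10 classes of 3′ UTR length), and the word occurs in the POSTN mRNA. Silencing of other mRNAs through the seed of the si-POSTN siRNA could give this. The outcome set down beforehand asked for at least 2 times the share of other genes with a similar 3′ UTR. The shares, not matched for length, were 53.2% and 28.3%, which falls short of that mark. A trend with base composition is argued against as the whole cause, since the 12 words of the same bases that do not overlap the site reached no lower t than −5.43, against −16.2 for CAACAAA (words that overlap it in part reached −9.16). The siRNA sequence is not in the labels and GCAACAAAA as a whole is absent from the POSTN mRNA searched (3373 bases), which holds TTGCAACAAA once, at bases 768 to 777, and CAACAAAAA once, at bases 2575 to 2583, both before its 3′ UTR, so the target position stays unknown. A response to the loss of periostin cannot be told apart from it for single genes, because 1 siRNA against POSTN was used: 32 genes that fell by 2-fold or more, XIRP1 among them, hold no 6-base part, and such genes could follow from periostin or from another silenced gene. For genes that rose 2-fold or more, release from silencing by the control siRNA is argued against if the supplier's catalogue sequence, which the labels do not give and which was not checked against a source here, has TTGTGTG as its seed match: it or a shift of it ranked no higher than 1037 of 16172 words, with an odds ratio of 0.967.

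The fall of the inflammatory list is not explained by sites in its own members, since the 10 without a 6-base part had a median of −1.05 (exact sign test, two-sided p = 0.00195). That test counts members as independent, whereas the list had an estimated correlation of 0.53, so its p value overstates the evidence. A candidate explanation is reduced interleukin-1 signalling: IL1R1 fell 3.60-fold, its 3′ UTR holds the whole site, and of 20 NF-kappaB target genes outside the list 18 fell and 0 rose by both adjustments (median −0.57; camera, adjusted p = 3.79e-09; adjusted p = 0.180 with an estimated correlation; 26.3% with a 7-base part), among them NFKBIZ, BIRC3 and VCAM1. This is a hypothesis found in the same data, and loss of periostin acting on NF-kappaB by another way was not tested. Restoring IL1R1 would test the part of that receptor, and an siRNA against POSTN with another seed would test the part of the seed. Neither alone would decide the hypothesis. For collagen chains the sites could not be separated from another cause, because only 4 members lack a 6-base part (median −0.23, exact sign test p = 0.625).

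For the rise of interferon-stimulated genes, the first test of release from silencing by the control siRNA decides nothing: the 23 members without a 6-base part of GGAGTGC, the leading word of higher genes, had a median of 0.51 (exact sign test, two-sided p = 6.6e-05), but 12.1% of genes that rose 2-fold or more hold that word and 14.1% of genes without a 2-fold change, so it marks no released genes. The 21 members without a 6-base part of TTGTGTG had a median of 0.65 (exact sign test, two-sided p = 0.000221), which argues against direct release at that site if the catalogue sequence is right. Both sign tests count members as independent, whereas the list had an estimated correlation of 0.86, so these p values overstate the evidence. A stronger innate response to the Stealth siRNA than to the control siRNA, whatever its target, cannot be told apart from an effect of losing periostin, because the design has 1 siRNA per target and the chemistry changes with the target. A second siRNA of the same chemistry could separate them.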
